A study of Homo sapiens with 8 samples.

How the data were processed

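Gene expression was measured in U2OS, a human osteosarcoma cell line, with Affymetrix human gene arrays hybridised with biotin-labelled total RNA. The sample labels put 4 arrays in the CDK9 siRNA group and 4 in the non-targeting control siRNA group. Per the labels' protocols, cells received siRNA at 10 nM and were collected 72 h later. The series' design text describes the replicates of each group as biological. A check for arrays with mostly identical values found 0 such pairs, so each array was counted as 1 replicate.

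The deposited table held log2 expression values of 33297 probe sets in 8 columns, with no missing value and a range of 2.01 to 14.7. Per the submitters' processing notes, RMA, Affymetrix Expression Console 1.1, limma and the hg19 genome build were used, but the role and order of these are not given in the sources used here. RMA corrects background, normalizes arrays by quantiles and summarises probes, which puts arrays that are processed together on a common scale. The deposited columns were not on a common scale. Replicate 1 of both groups had medians of 5.85 and 5.80, while the medians of the other 6 arrays lay between 6.99 and 7.04. Which arrays were normalized together is not given in the sources used here.

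Gaps in the numbers of the sample descriptions had already separated replicate 1 of both groups from replicates 2 to 4, before the values were examined. These were called array set 1 (2 arrays, 1 of each group) and array set 2 (6 arrays, 3 of each group). Whether the sets differ in culture, hybridisation or processing is not stated. Correlations between arrays across probe sets were 0.992 within set 1, 0.992 to 0.997 within set 2 and 0.975 to 0.981 between sets. The main axis of a principal component analysis held 93.6% of the variance and separated the sets, and the next held 3.14% and separated the groups.

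Gene names came from the platform annotation supplied with the table. It gave 1 symbol for 19460 probe sets, several for 1754 and none for 12083. Entrez identifiers of 19429 probe sets matched a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols and was used for names only. Coordinates were not used here, because that assembly is not the build named by the submitters. Probe sets with a single symbol entered the gene tests. Of the probe sets of a gene, the one with the highest mean over all arrays was kept, which left 18417 genes. For 769 genes with more than 1 probe set, 1043 other probe sets were set aside. In 78 of these both the kept and the other probe set passed the test, and 77 of the 78 went the same way. Genes whose mean lay in the lowest 30% (below 6.14) are called dim.

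Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05 over all genes tested). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The fit fixed before the data were examined had the group as its only term. It passed 0 genes, because the difference between array sets entered its residual. A fit with the array set as a block was among the alternatives fixed at the same time. The choice to lead with that fit was made after the column medians and the count of 0 had been seen. Each array set holds equal numbers of both groups, so log2 differences are the same in both fits and only their errors differ. Results below are from the fit with the array set as a block unless another is named, and both counts are given.

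Both fits were tested on simulated data for this comparison, with 18417 genes at the levels of the real arrays and 50 genes changed at each size. Without a block, 0% of changes of 1.2-fold, 1.5-fold, 2-fold and 4-fold were recovered. With the array set as a block, 30%, 90%, 98% and 100% were recovered, and 7 of the 166 genes called were unchanged ones. With the replicate number as a block, 8%, 76%, 94% and 100% were recovered, and 1 of 140 genes called was unchanged. The simulated arrays took their set differences and spread from the fit with the array set as a block. Each changed gene had the same change in both sets. The simulation thus favours that block by construction and cannot show which fit suits the real arrays. There, 395 genes passed a test for a group difference that differs between the sets, so the simulated error rates need not hold. A list shifted by 0.30 was recovered by the list test, with 0 of 23 unshifted lists called. Noise was drawn for each gene separately, so this cannot show how often lists whose genes vary together are called. In the real arrays the shifted list, G2 and mitosis, had an estimated correlation of 0.883.

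The replicate numbers of the titles recur in both groups. Deviations from the group means correlated across genes within each same-numbered pair at 0.822, 0.537, 0.494 and 0.607 for replicates 1 to 4, which is above the limit of 0.1 set for treating the numbers as pairs. Arrays of set 2 with different numbers correlated as well, at 0.405 to 0.561. After the mean of each group in set 2 was removed, the pairs 2, 3 and 4 correlated at 0.108, -0.011 and 0.170. The pairing therefore came mostly from the array set. Values with the replicate number as a block are given for the genes named in the text and the list tests whose call they change, and member counts with that block for some lists.

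A total of 24 gene lists (681 memberships, 627 of them measured) were fixed from textbook knowledge before the data were examined. Each was tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation. fry was run as an alternative. It asks whether the genes of a list move on balance in a single direction and does not compare them with other genes. The named genes were also chosen by a fixed rule: CDK9, CCNT1, CCNT2, CCNK, HEXIM1, MYC, MCL1, ATR and CHEK1 whatever their values, the 12 largest rises and 12 largest falls among genes past the threshold with all CDK9 siRNA arrays on the same side of all control arrays, and up to 4 members of each list. Applying this rule to the fit with the array set as a block, with the set difference removed before arrays were compared, was decided after seeing the data. Other list members that passed are named as examples of their list. Members of families with near-identical copies are marked as uncertain.

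Alternatives were other normalizations between arrays, a filter on dim genes, other uses of probe sets, other variance models, array weights, replicate blocks and leaving out each array in turn. Each of these combined with the array set as a block, array set 2 alone, quantile normalization within each set and the P-TEFb list without CDK9 were added after seeing the data. The CDK9 values were also compared with an exact permutation test. The number of arrays limits the precision, and the arrays give no read depth.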

Results

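The comparison asked how the transcriptome of U2OS cells changes when CDK9 is silenced by siRNA. CDK9 is the kinase of the positive transcription elongation factor P-TEFb, which releases paused RNA polymerase II. RNA of 4 cultures given CDK9 siRNA and 4 given a non-targeting siRNA was measured on 8 arrays, 72 h after transfection at 10 nM. Replicate 1 of both groups (array set 1) lay on a lower scale than replicates 2 to 4 (array set 2), so the 2 array sets were kept apart in the fit. Their separate values are given for those lists, and those genes named by a fixed rule, whose difference between the sets passed a test. Values of some others are given as well.

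CDK9 mRNA fell in every array given its siRNA. Its probe set (8158112) read 8.0, 9.03, 9.09 and 9.04 in replicates 1 to 4 of the CDK9 siRNA group, against 9.81, 10.9, 10.9 and 10.9 in the controls. The log2 difference was -1.82 ± 0.05 (SE, n = 4 per group), which leaves 28.4% of the control signal (95% confidence interval 26.4 to 30.5%). The share left was 28.5% in array set 1 and 28.3% in array set 2. CDK9 had the smallest adjusted p of all genes, 2.18e-07. An exact two-sided permutation test of the single value gave p = 0.0286 over all 70 arrangements and p = 0.05 over the 40 arrangements within array sets, each the smallest that the test can give. Without a block the adjusted p of CDK9 was 1, with the same log2 difference.

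**Figure D1:**
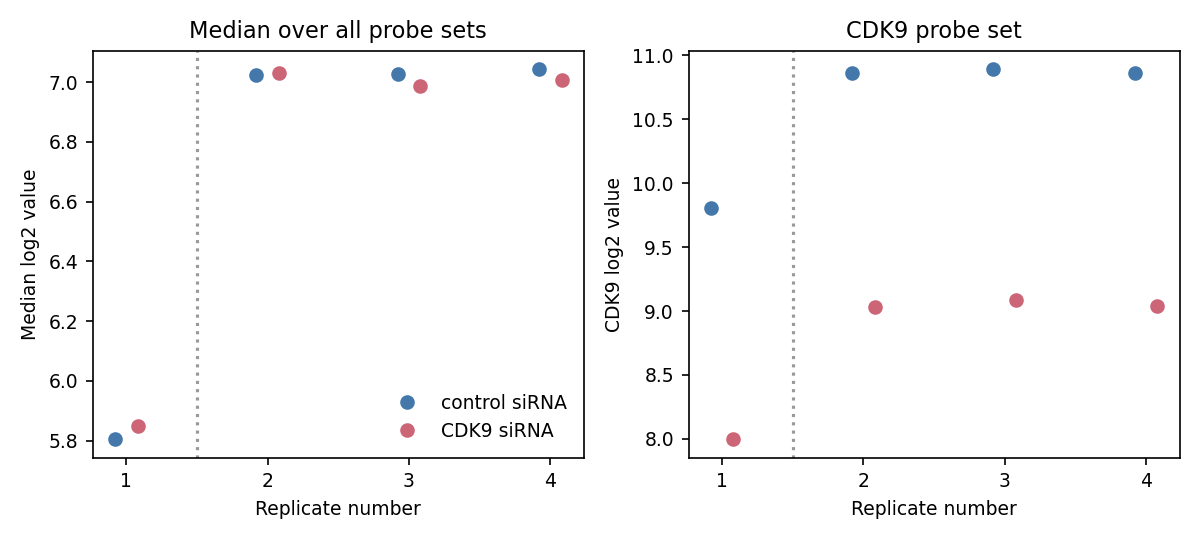
Median log2 value over 33297 probe sets (left) and log2 value of the CDK9 probe set (right) for each array, by replicate number, with control siRNA in blue, CDK9 siRNA in red and the dotted line between array sets 1 and 2. The replicate 1 arrays lie lower in both panels, and CDK9 lies lower with its siRNA in all 4 replicates.

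The largest rise was that of LCP1, which encodes the actin-bundling protein L-plastin, at 4.40-fold (log2 2.14 ± 0.11 SE, n = 4 per group, adjusted p = 2.01e-05). SPP1, the secreted matrix protein osteopontin, rose 2.82-fold. The rest of the 12 largest rises were SPX (2.46-fold), TMEM255A (2.31-fold), MLLT11 (2.26-fold), the chemokine CCL2 (2.24-fold), the immune checkpoint ligand CD274 (PD-L1, 2.19-fold), the laminin receptor subunit ITGA6 (2.14-fold), the growth factor PDGFC (2.12-fold), the chemokine CXCL8 (2.06-fold), GLP2R (2.0-fold) and RND3 (1.98-fold). The log2 differences of SPX, CCL2 and TMEM255A were 0.26, 0.32 and 0.68 in array set 1 and 1.64, 1.45 and 1.38 in array set 2.

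Besides CDK9 itself, the largest falls were those of SEMA3A, a secreted axon guidance factor (log2 -1.88 ± 0.21 SE, n = 4 per group, adjusted p = 0.000771), CFI, complement factor I (-1.69, a dim gene), and OLR1, a receptor of oxidised lipoprotein (-1.66). RIDA (-1.56), GASK1B (-1.51), the iron exporter SLC40A1 (-1.41), FOS (-1.41) and the complement receptor C3AR1 (-1.28) followed. The rest of the 12 were the collagen genes COL5A2 and COL3A1 and the matricellular gene CCN3, with COL5A2 at -1.30, COL3A1 at -1.27 and CCN3 at -1.20. For SEMA3A, CFI, OLR1, SLC40A1 and FOS the values were -0.87, -0.73, -2.21, -2.06 and -0.67 in array set 1 and -2.22, -2.01, -1.48, -1.20 and -1.66 in array set 2. The 23 genes of these lists other than CDK9 had adjusted p values up to 0.0048, and all of them also passed with the replicate number as a block and in array set 2 alone.

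Over all 18417 genes, 1239 rose and 1376 fell with the array set as a block, 14.2% of the genes tested. Most changes were small: the median was 1.24-fold among genes that rose and 1.23-fold among genes that fell. A change of 1.5-fold or more was seen for 105 and 138 genes, and one of 2-fold or more for 13 and 21. The fit without a block passed 0 genes in either direction in limma. Its smallest adjusted p was 0.104 (LCP1), and 28 genes were higher and 23 lower at an unadjusted p under 0.05. With the replicate number as a block, 813 genes rose and 875 fell, of which 795 and 856 were also called with the array set as a block.

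Array set 1 gave a check on genes called without it. In array set 2 alone (n = 3 per group), 1753 genes were higher and 1578 lower. Of these 3331 genes, 2480 (74.5%) had the same sign in the single pair of array set 1. By direction, 1216 of the 1753 higher and 1264 of the 1578 lower genes had the same sign there. Among the 294 that changed by 1.5-fold or more in set 2 it was 250 (85.0%), and among the 51 that changed by 2-fold or more it was 44 (86.3%). The median ratio of the set 1 difference to that in set 2 was 0.554, 0.651 and 0.446 for these 3 groups of genes. A ratio under 1 is expected of genes chosen by their set 2 values, and over all genes the differences had an SD of 0.263 in set 1 and 0.200 in set 2. Across all genes, which are not independent replicates, the differences in the 2 sets correlated at r = 0.367 (Spearman's rho 0.249). Lists of genes matched on signal level to the DNA replication genes had a median of -0.07 in set 1 and 0.02 in set 2. Such a shift of well-expressed genes in the set 1 pair can raise the agreement of falls and lower that of rises.

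**Figure D2:**
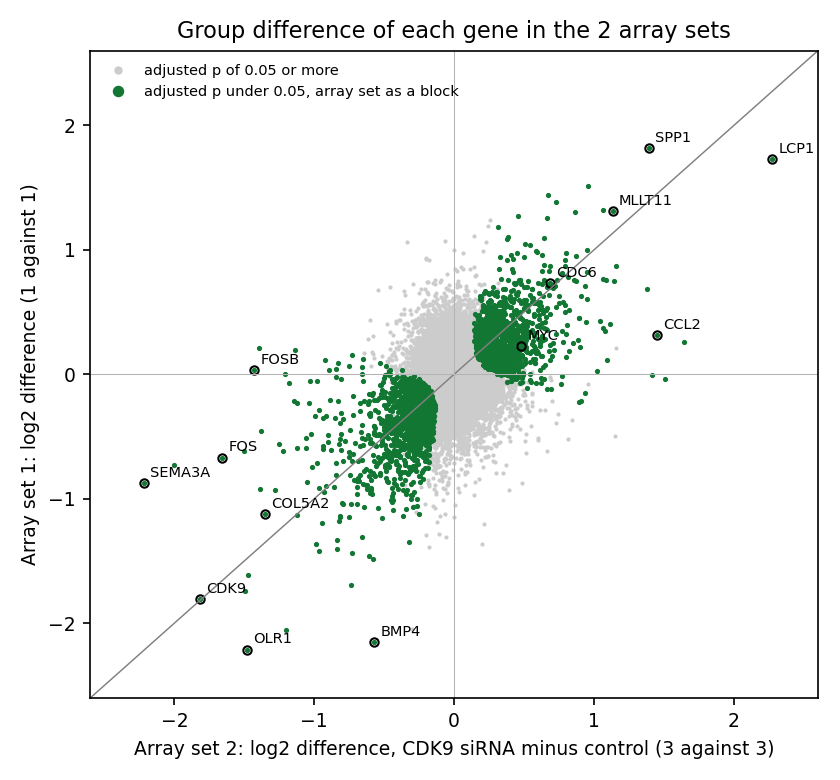
Log2 difference of each gene, CDK9 siRNA minus control, in array set 2 (x axis, 3 arrays against 3) and array set 1 (y axis, 1 against 1), with genes past adjusted p 0.05 in green, the rest in grey and the diagonal marking equal values. CDK9 lies on the diagonal at -1.82 and -1.81, while FOSB lies at -1.43 in set 2 and 0.03 in set 1.

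Partners of CDK9 moved by small amounts. CCNT2, a cyclin that pairs with CDK9, rose by 0.26 (adjusted p = 0.00885), while CCNT1 (0.15, adjusted p = 0.0731) and CCNK (-0.06, adjusted p = 0.499) did not pass. HEXIM1, an inhibitor of P-TEFb held in the 7SK complex, fell by 0.45 (adjusted p = 0.0209, and 0.0589 with the replicate number as a block), with -0.95 in array set 1 and -0.29 in array set 2. In the list of P-TEFb, 7SK and super elongation complex genes, 1 of 16 measured members rose and 5 fell. Adjusted over the list alone, 2 rose and 6 fell. The falls were CDK9, HEXIM1, the elongation factor ELL2 (-0.42), the 7SK capping enzyme MEPCE (-0.30) and MLLT1 (-0.29). A second ELL2 probe set gave -0.49. The list passed camera (adjusted p = 0.0205, and adjusted p = 0.294 with an estimated correlation), but without CDK9 the remaining 15 genes did not (adjusted p = 0.125). The list's median was -0.12 with CDK9 and -0.11 without it. In the list of other pausing, elongation and transcription-cycle kinase genes, 0 of 22 members passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.736). CCNC (0.19, adjusted p = 0.0526) and CDK12 (-0.15, adjusted p = 0.145) had the smallest p values there. Of 12 RNA polymerase II subunits, POLR2A, the largest subunit (-0.51 ± 0.05 SE), and POLR2F (-0.27) fell, 2 genes also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.348).

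Immediate-early and other short-lived transcripts fell as a list: 15 of 32 measured members fell and 1 rose (camera adjusted p = 7.38e-05, and adjusted p = 0.133 with an estimated correlation). Adjusted over the list alone, 15 fell and 2 rose. The largest falls were in AP-1 and early growth response genes, FOS (-1.41), FOSB (-1.06), EGR1 (-0.95) and FOSL2 (-0.87), with JUN at -0.52. SGK1 (-0.71), ID2 (-0.70) and ZFP36 (-0.46), which encodes a protein that destabilises mRNA, also fell. MYC was the member that rose, by 1.34-fold (log2 0.42 ± 0.06 SE, adjusted p = 0.00298). MCL1, another gene with a short-lived transcript, differed by 0.04 and did not pass (adjusted p = 0.668). FOSB differed by -1.43 in array set 2 and by 0.03 in array set 1.

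Extracellular matrix and collagen genes also fell as a list, with 15 of 33 lower and 2 higher (camera adjusted p = 7.38e-05, and adjusted p = 0.255 with an estimated correlation). The counts were the same adjusted over the list alone. Fibrillar collagens COL5A2 (-1.30 ± 0.06 SE) and COL3A1 (-1.27 ± 0.08 SE) led, followed by the gelatinase MMP2 (-0.96), fibronectin FN1 (-0.81), COL6A3 (-0.75) and MMP3 (-0.66, adjusted p = 0.0587 with the replicate number as a block). MMP3 differed by 0.04 in array set 1 and -0.89 in array set 2. The collagen cross-linking enzyme LOX (0.43) and TGFBI (0.23) rose. Of 18 osteoblast lineage markers, 4 fell and 1 rose, also adjusted over the list alone. The transcription factors RUNX2 (-0.60) and MSX2 (-0.56), COL1A1 (-0.51) and the growth factor BMP4 (-0.97) fell while SPP1 rose, and the list as a whole did not pass (camera adjusted p = 0.348). BMP4 lost its call with the replicate number as a block (adjusted p = 0.0615) and differed by -2.15 in array set 1 and -0.57 in array set 2.

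Targets of YAP/TAZ and TGF-beta signalling rose as a list, with 5 of 23 higher and 1 lower, and the same counts adjusted over the list alone (camera adjusted p = 0.0151, and adjusted p = 0.590 with an estimated correlation). The smooth muscle actin-binding protein TAGLN (0.88), endothelin EDN1 (0.58), CCN2 (0.54), CRIM1 (0.46) and CCN1 (0.36) rose. The kinase LATS2 fell by 0.30. The list's median was 0.02 in array set 1 and 0.11 in array set 2.

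p53 target genes fell as a list, with 6 of 30 lower and 0 higher over all genes and adjusted over the list alone (camera adjusted p = 0.0205, and adjusted p = 0.590 with an estimated correlation). TRIM22 (-0.98), TP53I3 (-0.56), the stress cytokine GDF15 (-0.38) and PLK3 (-0.30) fell most. The list's median was -0.21 in array set 1 and -0.07 in array set 2, where it did not pass (adjusted p = 0.122). TRIM22 differed by -1.70 in array set 1 and -0.74 in array set 2. Cytosolic ribosomal protein genes fell by small amounts, 5 of 29 over all genes and 10 adjusted over the list alone, where 1 rose (camera adjusted p = 7.38e-05, and adjusted p = 0.590 with an estimated correlation). Over all genes it was 2 with arrays centred on their medians and 1 with the replicate number as a block, while the list passed in both (adjusted p = 0.000194 and 0.000127). RPS19 fell by 0.29. RPL10A (-0.21), RPS9 (-0.19) and RPL13 (-0.19) lost their calls with the replicate number as a block (adjusted p = 0.0707, 0.0786 and 0.0984), and RPL13 in array set 2 alone (0.0631). A second RPS9 probe set gave -0.08, while other RPL13 probe sets gave -0.20 and -0.26. Ribosomal protein genes have many processed copies in the genome, so their probe sets are uncertain.

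DNA replication genes rose as a list, with 12 of 43 higher and 2 lower, and 14 and 2 adjusted over the list alone (camera adjusted p = 0.000211, and adjusted p = 0.645 with an estimated correlation). The origin licensing factor CDC6 rose 1.62-fold (log2 0.70 ± 0.05 SE), the clamp loader subunit RFC4 by 0.48 and the helicase subunit MCM6 by 0.34, while the polymerase subunit POLE2 (-0.39) and the cyclin CCNE1 (-0.21) fell. With arrays centred on their medians 8 members were higher and 1 lower. With the replicate number as a block, 3 members were higher and 0 lower, and the adjusted p values of POLE2 and CCNE1 were 0.0600 and 0.0590. The list's median was 0.00 in array set 1 and 0.12 in array set 2. In array set 1, lists of genes matched on signal level had a median of -0.07, and this list lay at percentile 94.0 of them. POLE2 differed by -0.82 in array set 1 and -0.25 in array set 2.

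Homologous recombination and Fanconi anaemia genes passed narrowly, with 4 of 26 higher and 0 lower, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.0455, and adjusted p = 0.645 with an estimated correlation). FANCE (0.33), EME1 (0.33 ± 0.07 SE), FANCL (0.31) and the helicase BRIP1 (0.24) rose. The list did not pass without a block (adjusted p = 0.0704), with the replicate number as a block (adjusted p = 0.0651, 2 members higher) or with arrays centred on their medians (adjusted p = 0.0550), and was also lost without CDK9 siRNA replicate 3 or 4 or control replicate 2 or 3 (adjusted p = 0.0863, 0.175, 0.122 and 0.117). The list's median was -0.05 in array set 1 and 0.13 in array set 2. FANCE and EME1 lost theirs with the replicate number as a block (adjusted p = 0.0867 and 0.0588), and FANCE in array set 2 alone (0.111).

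Of 30 ATR and ATM checkpoint genes, 4 rose and 1 fell, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.209). In array set 2 alone the list had adjusted p = 0.0129, and 0.385 with an estimated correlation. The list's median was -0.11 in array set 1 and 0.07 in array set 2. The ubiquitin ligase RNF168 rose by 0.39, the kinase CDC7 by 0.30, claspin CLSPN by 0.26 and RPA2 by 0.24. CDC7 and CLSPN lost their calls with the replicate number as a block (adjusted p = 0.0771 and 0.0572). The checkpoint kinases themselves did not pass, with ATR at 0.18 (adjusted p = 0.0568) and CHEK1 at 0.08 (adjusted p = 0.420). ATR passed when the arrays were quantile normalized again (adjusted p = 0.0272).

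G2 and mitosis genes did not pass with both array sets (camera adjusted p = 0.794). The hyaluronan receptor HMMR rose 1.76-fold, 1 of 36 members, also adjusted over the list alone. The list's median was -0.24 in array set 1 and 0.08 in array set 2, where it passed with the preset correlation (adjusted p = 0.000599) but not with an estimated correlation (adjusted p = 0.558). Of 43 replication-dependent histone genes, 6 rose and 1 fell, and 7 and 1 adjusted over the list alone (camera adjusted p = 0.110). H2BC12 (0.43), H2BC17 (0.38, dim), H2BC5 (0.29) and H2AC4 (0.28) led, and are uncertain because histone genes have near-identical copies. H2BC5 and H2AC4 lost their calls with the replicate number as a block (adjusted p = 0.109 and 0.0827), and H2BC17 and H2AC4 in array set 2 alone (0.0597 and 0.0566).

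**Figure D3:**
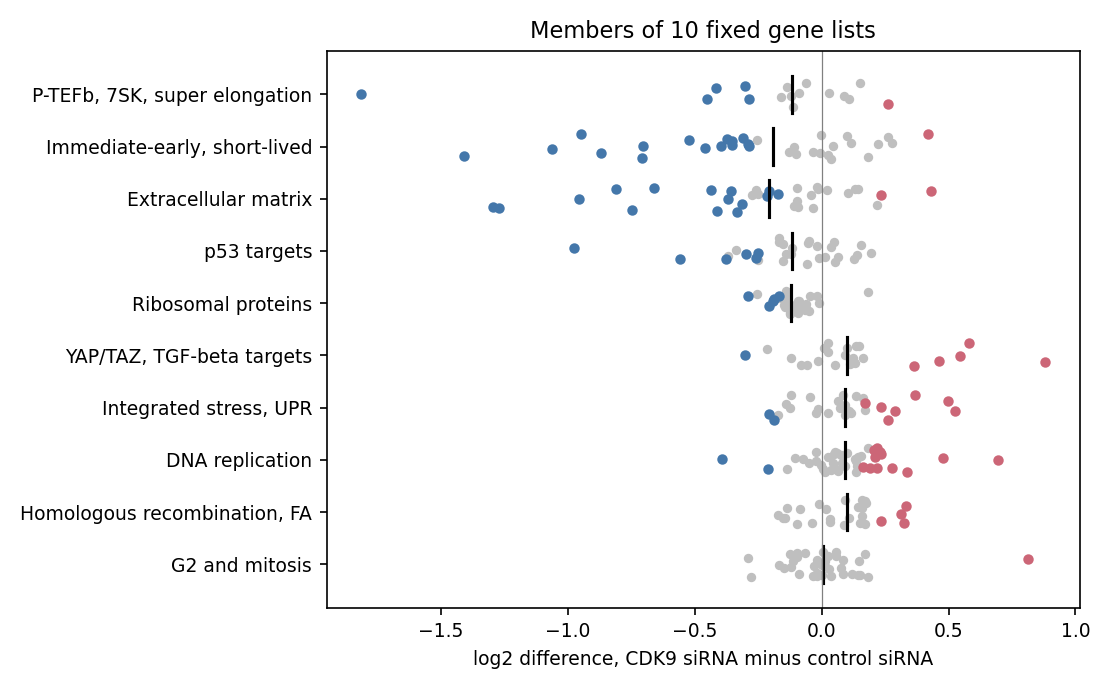
Log2 difference of each measured member of 10 fixed gene lists, CDK9 siRNA minus control, with members past adjusted p 0.05 in red (higher) or blue (lower), the rest in grey and a black bar at each list's median. Medians run from -0.21 for the extracellular matrix list to 0.10 for the YAP/TAZ and TGF-beta list, and 15 members each of the immediate-early and extracellular matrix lists lie among the falls.

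Integrated stress and unfolded protein response genes rose as a list, with 7 of 27 higher and 2 lower, and 8 and 2 adjusted over the list alone (camera adjusted p = 0.0226, and adjusted p = 0.645 with an estimated correlation). The lipoprotein receptor VLDLR (0.52) and the serine and folate enzymes SHMT2 (0.50), PHGDH (0.37) and MTHFD2 (0.29) led. The transcription factors ATF4 (0.17) and DDIT3 (0.23) rose, while the chaperones CALR (-0.21) and PDIA4 (-0.19) fell. With the replicate number as a block these 4 lost their calls (adjusted p = 0.0955, 0.0668, 0.0904 and 0.0782), and ATF4, DDIT3 and CALR did so in array set 2 alone (0.0571, 0.0734 and 0.0725). The list lost its call without CDK9 siRNA replicate 4 (adjusted p = 0.129) or control replicate 2 (adjusted p = 0.0508). Of 20 heat shock genes, 4 rose and 2 fell, and 5 and 2 adjusted over the list alone (camera adjusted p = 0.219). Heme oxygenase HMOX1 (-0.94) fell, and CHORDC1 (0.59), HSPB8 (0.52) and DNAJB4 (0.40) rose.

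NF-kappaB targets moved both ways, with 4 of 28 higher and 3 lower, and 4 and 4 adjusted over the list alone (camera adjusted p = 0.825). CCL2, CXCL8 and CCL20 (0.81, dim) rose, while the prostaglandin synthase PTGS2 (-0.90) fell. The PTGS2 difference in array set 1 minus that in array set 2 was 1.11, so its fall came mostly from array set 2. Among 39 type I interferon response genes 2 rose and 2 fell, and 2 and 1 adjusted over the list alone (camera adjusted p = 0.985). IFIT2 rose by 0.78 and IFI44 (dim) by 0.57, and IRF9 fell by 0.37 and ISG20 by 0.30. The IFIT2 difference in array set 1 minus that in array set 2 was -0.99, so its rise came mostly from array set 2. ISG20 did not pass with the replicate number as a block (adjusted p = 0.0714) or in array set 2 alone (0.119). The NF-kappaB list has a negative median and a positive mean, the interferon list a positive median and mean but a test in the lower direction, and the apoptosis list a positive median and a negative mean.

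Among 20 BCL2 and IAP family genes, PMAIP1 (NOXA) rose by 0.25 and XIAP fell by 0.25, also adjusted over the list alone (1 higher and 1 lower, camera adjusted p = 0.931). XIAP had adjusted p = 0.0901 with the replicate number as a block. Of 18 cholesterol synthesis genes, STARD4 rose (0.31, adjusted p = 0.0746 with the replicate number as a block), 0 passed adjusted over the list alone, and the list did not pass (camera adjusted p = 0.209, and in array set 2 alone 0.0298, or 0.670 with an estimated correlation). Of 37 nuclear-encoded oxidative phosphorylation genes, SDHD (0.20) rose and NDUFB10 (-0.27), NDUFS3 (-0.22) and SDHA (-0.20) fell, 0 passed adjusted over the list alone, and the list did not pass (camera adjusted p = 0.248). All 4 lost their calls with the replicate number as a block (adjusted p between 0.0666 and 0.0953), and NDUFS3 and SDHA in array set 2 alone (0.0551 and 0.0877). A second SDHD probe set gave 0.12.

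Markers of other cell types did not pass as lists. Of 17 epithelial markers, JUP fell by 0.39 and EPCAM (dim) rose by 0.32, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.605). CD68 fell by 0.31 among 16 leukocyte markers, 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.619). TEK (dim) rose by 0.30 among 12 endothelial markers, 1 and 0 adjusted over the list alone (camera adjusted p = 0.416). EPCAM and CD68 lost their calls with the replicate number as a block (adjusted p = 0.0841 and 0.0645), and a second EPCAM probe set gave 0.09.

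The difference between array sets itself passed camera at the preset correlation for 8 lists, all lower in set 1, and for 0 with an estimated correlation. Adjusted p was 4.78e-17 for G2 and mitosis, 0.00534 for DNA replication and for ATR and ATM, 0.00825 for interferon, 0.00839 for p53 targets and for oxidative phosphorylation, 0.0118 for homologous recombination and 0.0418 for cholesterol synthesis. The medians of the interferon, oxidative phosphorylation and cholesterol lists were -0.08, -0.15 and -0.03 in array set 1 and 0.03, -0.02 and 0.08 in array set 2. Lists of genes matched on signal level had medians of 0.02, -0.06 and -0.06 in array set 1 and -0.02, 0.02 and 0.01 in array set 2. Genes of the same level thus shared part of the set difference for oxidative phosphorylation and cholesterol, but not for interferon. The list test does not allow for signal level. These tests assume that the 2 arrays of set 1 vary like those of set 2.

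In all, 9 of the 24 lists passed camera with its preset correlation, 4 higher and 5 lower, and 0 passed with an estimated correlation. Among the 5 lower lists, P-TEFb holds the siRNA target CDK9 and did not pass without it (camera adjusted p = 0.125). Groupings of the arrays other than by siRNA, given below, passed up to 11 lists in the same preset test. fry passed 9 lists in a single direction, 3 higher and 6 lower, and 18 when both directions counted. These were not the same 9 lists. Homologous recombination did not pass fry (adjusted p = 0.129), while RNA polymerase II subunits passed it in the lower direction (adjusted p = 0.0252).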

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

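The test of an overall scale difference between the array sets, the test of cycling cells and the use of 20 splits for counts with the array set as a block were settled after the results they measure had been seen, and the other tests below were set before. The cycling-cell explanation was first written as any different cell-cycle state of a culture, with a bound on array set 1 alone.

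Replicate 1 stood far from the other replicates in both groups. Its gap to the nearest other array, divided by the group's whole range, was 0.985 for the array medians of the control group and 0.964 for those of the CDK9 siRNA group. For the CDK9 probe set the ratios were 0.966 and 0.949; all 4 exceed Dixon's 95% critical value for groups of 4. Of 200 pairs of a named gene and a group, 150 had replicate 1 beyond that value and 0 had another replicate beyond it. List means had replicate 1 beyond it in 48 of 48 pairs of a list and a group. Chance marks about 1 in 20 such groups, but these pairs are not separate tests. The lower scale of the replicate 1 arrays as a whole enters all of them, so they restate that shift. A signal was also present outside the named genes. Of 13837 probe sets with several symbols or no symbol in the annotation given, 306 passed with the array set as a block (151 higher and 155 lower, 2.21% against 8.45% of the probe sets with a single symbol).

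No gene passed without a block and 2615 passed with the array set as a block. A different overall scale of the 2 arrays of set 1 would be removed by quantile normalization of all arrays, yet this recovered 7.92% of the 2615 genes without a block, well under the 50% set as the bound. Differences between the sets that are specific to each probe set remained after quantile normalization, and correlated across genes at 0.819 between the control and the CDK9 siRNA arrays. Separate processing of the 2 sets may therefore account for the low count without a block. Whether culture, hybridisation or normalization differed between the sets stays open, since the labels do not say. There are 35 ways to split the 8 arrays into groups of 4. Without a block the real split gave 0 genes and the highest other split 0, so all 35 gave as many. A count of 0 fixes that outcome, and it says nothing about chance. With the array set as a block, the comparable splits are the 20 that part the 2 arrays of set 1, as the real split does. The real split gave 2615 genes against 10 in the highest other, and 34 genes with 2-fold changes against 0. In each case 1 of the 20 splits, the real split, gave as many, and 20 splits are too few for a share under 5%.

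For the gene lists without a block chance is not excluded, since as many lists as in the real split passed camera in 13 of the 35 splits (real 8, highest other 10). With the array set as a block, 3 of all 35 splits gave as many (real 9, highest other 11). Among the 20 that part the 2 arrays of set 1 it was 1, the real split (highest other 8), again too few splits for a share under 5%. Each of the other splits among these 20 passed between 1 and 8 lists. The preset test thus passed lists on groupings other than the siRNA groups. A passed list is therefore not by itself evidence of a response to the siRNA. The members of a list that passed come from the same arrays and can vary together, so their counts are not separate support for its direction.

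G2 and mitosis genes lay lower with CDK9 siRNA in the set 1 pair (median -0.24) and higher in array set 2 (median 0.08). The difference between sets passed a test of the interaction with a preset correlation (camera adjusted p = 4.78e-17), but not with an estimated correlation (adjusted p = 0.389), and it assumes that the 2 arrays of set 1 vary like those of set 2. A trend of the set 1 pair with signal level is argued against, because the median lay at percentile 0 of 10000 lists matched on signal level. Fewer cycling cells in 1 culture of set 1 may account for it and could be neither excluded nor shown. DNA replication genes were lower in set 1 relative to set 2 as well (medians 0.00 and 0.12, camera adjusted p = 0.00534), but not past the threshold with an estimated correlation (adjusted p = 0.646). Level-matched lists had medians of -0.07 in set 1 and 0.02 in set 2. Much of that difference is therefore shared by other genes of the same level, and it says little about cycling cells. Within the set 1 pair they lay at percentile 94.0 of level-matched lists, the earlier bound. That value excludes nothing, because these genes lay at percentile 99.98 in array set 2, so that a smaller rise in set 1 need not bring them below other genes. A shift between cell-cycle phases in a single culture was not tested, and both rest on 1 array per group.

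Immediate-early genes fell together (15 of 32). A trend of the group difference with signal level is argued against, because the list's median lay at percentile 0 of 10000 level-matched lists. Handling of the cultures at harvest can move these genes between replicates. The median residual SD of the members in array set 2 lay at percentile 95.7 of level-matched lists, between the bounds set for the test, so handling could neither be excluded nor shown. The silencing of CDK9 itself stays among the open explanations.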

How the results depend on the processing

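All alternatives that combine another choice with the array set as a block, including each left-out array there, and array set 2 alone were added after seeing the data, while those without that block were fixed before. The fold changes did not depend on the block, so the calls changed through their errors, and the cause of other changes was not tested. Counts are given as higher and lower, then higher and lower by 2-fold or more. The fit without a block passed 0, 0, 0 and 0 genes, with CDK9 at -1.82 (adjusted p = 1). In the settings that follow, up to array weights, CDK9 passed at -1.82 or -1.81. The array set as a block gave 1239, 1376, 13 and 21. The replicate number as a block gave 813, 875, 13 and 21, and as a random effect 1310, 1342, 13 and 21. Without a block, quantile normalization gave 119, 88, 7 and 6, median centring 52, 41, 6 and 6 (CDK9 -1.81), cyclic loess 108, 84, 7 and 6 (CDK9 -1.81), and array weights 2192, 1977, 21 and 35, where the weights nearly removed replicate 1. The dim filter, the mean of probe sets, every probe set, a trended robust variance and no moderation left 0 genes, CDK9 included. Leaving out each array in turn without a block gave 0 to 1 genes higher, also 0 to 1 by 2-fold or more, the gene being found without CDK9 siRNA replicate 1, and 0 lower. CDK9 differed by -1.55 to -2.08 there and did not pass.

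With the array set as a block, leaving out each array gave 714 to 1753 genes higher, 806 to 1578 lower and 11 to 20 higher by 2-fold or more. Counts moved by over 1.5 times without CDK9 siRNA replicate 3 (771 and 883), control replicate 3 (714 and 806), control replicate 4 (814 and 871), control replicate 2 (796 higher) and either replicate 1, which equals array set 2 alone (20 higher by 2-fold or more). Array weights gave 20 there as well. No scaling moved the median of all genes by 0.1, and genes that rose made up 45.2 to 52.6% of calls over the settings with the block. Normalization puts arrays on a common centre, so these values cannot show whether mRNA as a whole changed. The rises and falls given here are relative to the other genes. The count of lists was 7 to 11 in the settings run with camera's preset correlation. It fell to 0 with an estimated correlation, both without a block and with the array set as a block. With that block the estimated correlations of the immediate-early and P-TEFb lists were 0.0071 and 0.0058, under the preset of 0.01. A larger correlation between genes therefore does not account for the loss of these calls. The other lists that had passed had estimates from 0.043 (extracellular matrix) to 0.310 (DNA replication). fry passed 0 lists without a block and 9 with it. The 9 lists that passed camera with the preset correlation, P-TEFb with CDK9 among them, kept their direction under each scaling with the array set as a block. Of these, 9 of 9 passed under both quantile normalizations and cyclic loess and 8 of 9 under median centring. List tests were not run for the random effect, no moderation and every probe set. No named gene reversed its call. Of the 100 genes named by the fixed rule, 21 lost their call with the replicate number as a block, and that block changed no call of a list other than homologous recombination. Summed over the 24 lists, 59 members higher and 72 lower became 36 and 44 with it, among them 15 lower extracellular matrix genes that became 11, NF-kappaB targets from 4 and 3 to 3 and 1, histones from 6 and 1 to 2 and 0, and heat shock genes from 4 and 2 to 3 and 1. CCNT1, ATR and CCNC, which did not pass, did under a dim filter, a trended variance or cyclic loess (CCNT1 adjusted p = 0.0371, 0.0201 and 0.0468). Without moderation 25 named genes lost their call. Of these, 9 had kept it with the replicate number as a block: SPX, FOSB, IFIT2, PTGS2, FANCL, H2BC17, IFI44, DNAJB4 and TEK (adjusted p between 0.0533 and 0.0938). Leaving out a single array lost 7 to 22 named calls: 7 without either replicate 1, 12, 22 and 13 without CDK9 siRNA replicates 2, 3 and 4, and 16, 19 and 20 without control replicates 2, 3 and 4. In all 26 named genes lost their call in at least 1 of these, 6 of which had kept it with the replicate number as a block. The 6 were FANCL without CDK9 siRNA replicate 3 (adjusted p = 0.0528), BRIP1 without control replicate 2 (0.0542), RPA2 without control replicate 3 or 4 (0.0540 and 0.0569), PMAIP1 without CDK9 siRNA replicate 3 or control replicate 2 (0.0542 and 0.0511), TEK without CDK9 siRNA replicate 3 or 4 or control replicate 2 or 3 (0.0516 to 0.0816), and H2BC17 without any 1 array other than CDK9 siRNA replicate 4 and control replicate 3 (0.0580 to 0.0632). Dim genes carry a low signal over background, which limits the sizes given for them.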

Other observations

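Families of genes that share a symbol stem were compared after the fixed lists, with the same test, for 137 stems of 15 or more genes. Protocadherin beta genes, which encode neural cell adhesion proteins, fell in 13 of 18 cases and rose in 0 (median -0.54, camera adjusted p = 1.02e-10, and adjusted p = 0.156 with an estimated correlation). PCDHB2 (-0.86), PCDHB5 (-0.86) and PCDHB11 (-0.85) were the lowest, with family medians of -0.47 in array set 1 and -0.58 in array set 2. Of the 18 genes 8 were dim. Metallothionein genes, whose products bind zinc and copper, rose in 8 of 15 cases and fell in 0 (median 0.33, camera adjusted p = 2.23e-06, and adjusted p = 0.795 with an estimated correlation), led by MT1E (0.84), MT1G (0.54) and MT1DP (0.53), with family medians of 0.43 in array set 1 and 0.35 in array set 2. Members of both families are related in sequence, so probe sets of different members may read the same transcripts and the counts of members are uncertain. The counts include genes with pseudogene symbols, PCDHB17P, PCDHB18P, MT1DP and MT1P3. The metallothioneins MT3 (0.01) and MT4 (0.02) did not pass.

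Among histone lysine demethylase genes, 7 of 18 fell, including KDM7A (-0.59) and KDM5B (-0.54), and 1 rose, KDM4D (0.20, and adjusted p = 0.0762 with the replicate number as a block). The family passed camera (adjusted p = 0.000414, and adjusted p = 0.795 with an estimated correlation). Of 22 matrix metalloproteinase genes 7 fell, with MMP2 at -0.96 and MMP12 (dim) at -0.89 (camera adjusted p = 0.00561, and adjusted p = 0.907 with an estimated correlation), of which MMP2 and MMP3 also belong to the extracellular matrix list. Of the 22 genes 10 were dim. The family's median was 0.00 in array set 1 and -0.16 in array set 2. Of 494 ZNF zinc finger genes 55 fell and 11 rose (camera adjusted p = 0.00808, and adjusted p = 0.907 with an estimated correlation). Of 23 nucleoporin genes 4 rose, NUP210 by 0.67 (camera adjusted p = 0.0273, and adjusted p = 0.907 with an estimated correlation). The other 5 stems past the threshold were RPL, KRTAP, OR, ZFP and TAF. Dim genes made up 33 of 68 KRTAP and 352 of 361 OR genes. In all, 11 stems passed with the preset correlation and 0 with an estimated correlation, and the medians of the 11 kept their direction under each scaling with the array set as a block. In array set 2 alone 4 of the 11 did not pass: KRTAP, OR, ZFP and TAF (adjusted p = 0.116, 0.0591, 0.130 and 0.210). The medians of the demethylase, ZNF and nucleoporin families were -0.18, -0.06 and 0.02 in array set 1 and -0.18, -0.07 and 0.08 in array set 2. The genes named here were chosen after their values were seen.

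Single genes also differed between the array sets. In a fit with an interaction of group and array set, 395 of 18417 genes passed, with a smallest adjusted p of 0.00829, on the assumption that the set 1 arrays vary like those of set 2. Of the 100 genes named by the fixed rule 13 were among them: BMP4 (adjusted p = 0.00829), CCL2 and TRIM22 (both 0.0142), CFI (0.0162), SLC40A1 (0.0163), FOSB (0.0223), OLR1 (0.0244), HEXIM1 (0.0274), SPX (0.0288), TMEM255A (0.0345), FOS (0.0355), SEMA3A (0.0376) and POLE2 (0.0465).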
